A study of Homo sapiens with 9 samples.

How the data were processed

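RNA splicing was measured by RNA-seq in 9 libraries from 3 human cell lines, with 3 replicate cultures per line. All lines come from a Flp-In 293 clone labelled Rbfox2 KO#7. The lines are that clone itself (KO), the same clone with FLAG-tagged wild-type Rbfox1 (WT) and the same clone with FLAG-tagged Rbfox1 carrying F125A (F125A). Per the labels, all cultures received doxycycline for 48 h, and stranded poly-A libraries were sequenced as paired reads of 100 nt.

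The authors deposited 15 event tables in the layout of rMATS, a tool that counts reads for and against alternative splicing events. They cover 3 comparisons (WT against KO, F125A against KO and WT against F125A) for 5 event types: cassette exons, alternative 3′ splice sites, alternative 5′ splice sites, mutually exclusive exons and retained introns. The genome build is hg38 in the submitters' processing notes. The rMATS version, the aligner and the annotation are not given in the sources used here. Per the file headers, each event has reads of the inclusion form and of the skipping form, and inclusion levels, each as a list of 3 libraries in 1 cell. These lists have no single unit, so the other kind of unit was recorded for them: read counts for both forms, and a fraction for the inclusion level. Per the file headers, each event also has a p-value, a false discovery rate (FDR) and, as a score, the difference of mean inclusion levels between the groups. For cassette exons the inclusion form's effective length was the exon length plus 99 nt, so reads inside the exon body count beside junction reads.

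A spreadsheet had fused many read lists into 1 number. Of 1700322 pairs of lists (1 event in 1 line, both forms), 946166 (55.6%) held a fused list. They were split back by trying every division of the digits and keeping those whose inclusion levels match the deposited ones within 0.00051. A single division matched in 638951 (67.5%), and 994 had no match and were left out. In 306221 (32.4%) several divisions matched, and the one with the most even read numbers among libraries was taken. This rule chose the matching division in all of 631420 cases where only 1 matched and more than 1 was possible.

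Percent spliced in (PSI) was computed per library as the length-corrected fraction of the inclusion form. Differences are first line minus second line, and their sign was checked against the deposited differences. Events were tested with a mean of at least 20 reads per library and at least 10 reads of each form in total. Of events with the same regulated region, the one with most reads was kept. The test was a quasi-binomial logistic model of inclusion against skipping reads per library, with an F test, run in R 4.3.3. Its dispersion was moderated across events with limma 3.58.1 (squeezeVar, with a trend on depth) and not allowed below 1. P values were adjusted by Benjamini-Hochberg within each table and event type. A call required an adjusted p below 0.05 and a difference of mean PSI of at least 0.1. All p values of named exons come from this model and are two-sided. The order of libraries in the lists is not labelled, so libraries are named by their place in the list.

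The model, the filters, the 10 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named exons are, per comparison, the 10 largest increases and 10 largest decreases among called exons whose libraries do not overlap (1 per gene), and up to 4 called members of each gene list. For the other event types they are the 2 largest changes in each direction. RBFOX1, RBFOX2 and RBFOX3 were named in any case. Some exons that meet this rule are not reported here. Exons that fall outside this rule are marked in the text as chosen after their values were seen.

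Gene lists, exon length and exon frame were tested with Fisher's exact test, two-sided. Background exons for length and frame were tested exons without a call and with a mean PSI between 0.05 and 0.95. The overlap of the 2 comparisons against KO was set beside unchanged lines simulated against the same KO libraries. Other splits of the 6 libraries of each comparison were tested (10 splits each). Alternatives were PSI thresholds of 0.05 and 0.2, coverage minimums of 10, 50 and none, every event, no dispersion floor, no depth trend, the deposited FDR, limma on logit PSI (0.5 added to each form), 1 fit over all 3 lines, events with lists intact or split in only 1 way, and each library left out. Exon ends and coding status were looked up in GENCODE 29. Positions are 1-based.

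The test was run on data simulated from the read depths and dispersions of the real tables, with 50 changed cassette exons per size. For a PSI change of 0.2 it called 28% (WT against KO), 40% (F125A against KO) and 26% (WT against F125A) of them. For a change of 0.4 it called 54%, 74% and 70%. No simulated change was called in the wrong direction. Of unchanged exons, 1 of 55102, 7 of 51480 and 2 of 56036 were called. Reads were drawn with the moderated dispersions of the test itself. These counts therefore do not measure the error rate in the real data, where single exons may vary more.

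Tests of motifs near the exons were planned and not run, because a genome sequence was not used here. edgeR and DESeq2 were not run, since the read lists are not count columns of single libraries. A block for the replicate number was not fitted, because the lists do not name the replicates. Gene expression was not analysed here. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for tables, exact tests and figures.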

Results

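Splicing was compared among 3 lines derived from Flp-In 293, an HEK293-derived cell line with a recombination site for integrating a transgene. The KO line lacks Rbfox2 by its label. Rbfox2 belongs to a family of splicing regulators that bind RNA through an RNA recognition motif and act on exons of cytoskeletal, synaptic and signalling genes. The WT line expresses wild-type Rbfox1, a member of the same family, in the KO background. The F125A line expresses Rbfox1 in which a phenylalanine of the RNA recognition motif is changed. The design text states that both proteins reached similar levels by immunoblot. Each line was grown as 3 replicate cultures, giving 9 libraries.

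Reads assigned to cassette-exon events in the table of the WT and KO lines numbered 126347328, 131676671 and 122789373 in the WT libraries and 134047091, 126204329 and 130110540 in the KO libraries. In the table of the F125A and KO lines, the F125A libraries had 107596002, 104762396 and 120964980. A read can count in several events, so these sums give relative depth within a comparison and are not library totals. The comparisons list different events, so sums from different ones cannot be set side by side. In the comparison of the WT and F125A lines the sums were 132197012, 137731809 and 128404514 (WT) and 117914755, 114810536 and 132376960 (F125A). Inclusion is given below as PSI, the fraction of transcripts that include the exon, as mean ± SD with n = 3 libraries per line throughout. The number of reads behind an exon, given below for the main ones, limits the precision of its PSI. Over the 11127 to 12285 well-covered variable exons of a table, PSI correlated between libraries of the same line at r of 0.95 to 0.966. Between lines r was 0.939 to 0.955. These correlations are across exons, which are not independent replicates.

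RBFOX2 transcripts were still present in all lines. The RBFOX2 event with most reads, an alternative 3′ splice site, had 509, 495 and 496 reads in the KO libraries, 484, 749 and 708 in the WT libraries and 888, 796 and 583 in the F125A libraries. Where the gene was altered in the KO clone is not given in the sources used here. RBFOX1 had 0 events listed in any table, so the transgene was not measured here. RBFOX3 had between 19 and 69 reads per library in its deepest event. Of 15 marker genes of other lineages, 13 had no event listed, and COL1A1 had the most reads, with a mean of 26.5.

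The WT line was compared with the KO line to find the exons that differ in the presence of wild-type Rbfox1. With 1 line per construct, a difference between separately grown lines cannot be told apart from an effect of the protein. The p values rest on the spread among cultures, moderated for each exon towards that of events with similar depth. An exon whose own cultures vary widely can therefore still have a small p. ACTN2 encodes an alpha-actinin that cross-links actin filaments, and its 79-nt exon rose from a PSI of 0.0254 ± 0.0440 in the KO line to 0.814 ± 0.0585 in the WT line. The 2400-nt exon of RTN4, which encodes a reticulon that restrains axon growth, rose from 0.276 ± 0.0919 to 0.835 ± 0.0515. PTBP2 encodes a neuronal repressor of exons, and its 34-nt exon rose from 0.188 ± 0.0781 to 0.672 ± 0.181. The 51-nt exon of CLASP2, which encodes a protein of growing microtubule ends, rose from 0.00978 ± 0.00416 to 0.492 ± 0.0153. The 69-nt exon of SYNE2, which encodes a linker of nucleus and cytoskeleton, rose from 0.0203 ± 0.0222 to 0.487 ± 0.0285.

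Other exons were lost from transcripts in the WT line. TPM1 encodes a tropomyosin with alternative internal exons, and its 76-nt exon fell from 0.965 ± 0.0373 to 0.167 ± 0.00449. The 37-nt exon of ATP5F1C, which encodes a subunit of the mitochondrial ATP synthase, fell from 0.995 ± 0.00213 to 0.682 ± 0.0263. A 3-nt exon of CYTH1, which encodes an activator of ARF GTPases, fell from 0.95 ± 0.0203 to 0.314 ± 0.0773. The 57-nt exon of INF2, which encodes a formin, fell from 0.790 ± 0.133 to 0.338 ± 0.0699.

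In hg38 the exon of ACTN2 (ENSG00000077522.15) spans chromosome 1 from 236727678 to 236727756 on the + strand. The exon of TPM1 (ENSG00000140416.24) spans chromosome 15 from 63061198 to 63061273 on the + strand, and that of ATP5F1C (ENSG00000165629.20) spans chromosome 10 from 7806974 to 7807010 on the + strand. The exon of PTBP2 (ENSG00000117569.20) spans chromosome 1 from 96806419 to 96806452 on the + strand. GENCODE 29 annotates all 4 as coding exons. A library had on average 148 reads for the ACTN2 exon, 133 for PTBP2, 536 for TPM1 and 2119 for ATP5F1C. Adjusted p was 1.27e-10 for ACTN2, 2.10e-06 for PTBP2, 1.38e-59 for TPM1 and 6.54e-80 for ATP5F1C.

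Of 55302 cassette exons tested between the WT and KO lines, 448 in 335 genes were called. Inclusion was higher in the WT line for 330 of them and lower for 118. The median size of the change was 0.203. The libraries of the lines did not overlap in 430 of the called exons, and in 13.9% of all tested exons, where chance gives at most 10%. Libraries tied in PSI count as overlapping, so the chance share is lower where ties occur. With the deposited FDR in place of this test and the same size of change, 3363 exons were called, 1657 higher and 1706 lower. With limma on logit PSI 124 were called. Of the 176 events called and named by rule in the 3 comparisons, limma kept 38 past its threshold, and the deposited FDR kept all 176.

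Among the gene lists, cytoskeletal genes held the most genes with a called exon. Of 82 tested genes of cytoskeleton and adhesion, 42 had a called exon (36 with a higher and 8 with a lower one), against 2.92% of other genes (Fisher's exact test, adjusted p 7.03e-40). Of 67 kinase and GTPase signalling genes, 19 had one (adjusted p 8.83e-13), among them GIT2, a regulator of focal adhesions, whose 90-nt exon rose from 0.188 ± 0.0650 to 0.588 ± 0.0823. Of 64 trafficking genes 15 had one (4.29e-09), of 77 chromatin and transcription genes 10 (0.000427) and of 22 mitochondrial genes 4 (0.00772). The 189-nt exon of the chromatin remodelling gene BPTF rose from 0.339 ± 0.0733 to 0.693 ± 0.0547. The 60-nt exon of MFF, which encodes a mitochondrial fission factor, rose from 0.237 ± 0.0910 to 0.458 ± 0.00902. A 3-nt exon of the mitochondrial channel gene VDAC3 rose from 0.000191 ± 0.000331 to 0.128 ± 0.0105. Of 30 neuronal channel and synapse genes 6 had a called exon (0.000640), among them APP, whose 57-nt exon rose from 0.138 ± 0.0112 to 0.326 ± 0.0164. Of 64 genes of splicing regulators 5 had one (0.0756).

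Of 36 tested genes known for Rbfox-regulated exons, 20 had a called exon (adjusted p 3.30e-20), and 34 of the 37 such genes found are also in another list. Adjusted over the list alone, the genes with a called exon numbered 24 of the known targets, 47 of cytoskeleton, 22 of signalling, 19 of trafficking, 12 of chromatin, 4 mitochondrial, 7 neuronal and 7 splicing. Of 153 exons in 7 genes of LASR, a complex of splicing regulators that associates with Rbfox proteins, 0 were called by the quasi-binomial model. At an unadjusted p below 0.05 and a change of 0.1 the count was 0, and it was 0 with the deposited FDR and with limma. Of all tested exons only 448 of 55302 were called by the quasi-binomial model. Its 0 calls among 153 exons therefore do not show that LASR genes are spared. The lists were drawn largely from genes known for regulated cassette exons, so their share of calls against other genes says nothing about a function of the affected genes. In all 3 comparisons, genes of the lists also had more tested exons than other genes, which raises their chance of a call. For cytoskeleton the median was 9 against 4 in WT against KO.

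Short exons were more frequent among called than among uncalled exons. Among exons with higher inclusion in the WT line, 39 of 330 (11.8%) were at most 27 nt long, against 1.76% of the uncalled variable exons (odds ratio 7.48, Fisher's exact test, adjusted p 2.31e-19). Their length was divisible by 3 in 70.3%, against 39.1% (odds ratio 3.69, adjusted p 7.82e-29). Among exons with lower inclusion, 9 of 118 (7.63%) were short (adjusted p 0.000314) and 56.8% were divisible by 3 (0.000161). The 24-nt exon of RAPGEF6, which encodes an activator of RAP GTPases, rose from 0.0198 ± 0.0344 to 0.387 ± 0.0770. P values of this family were adjusted over 18 tests. Some exons overlap or share a gene (the 448 called exons lie in 335 genes). They are not independent, so these p values may be too small.

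**Figure D1:**
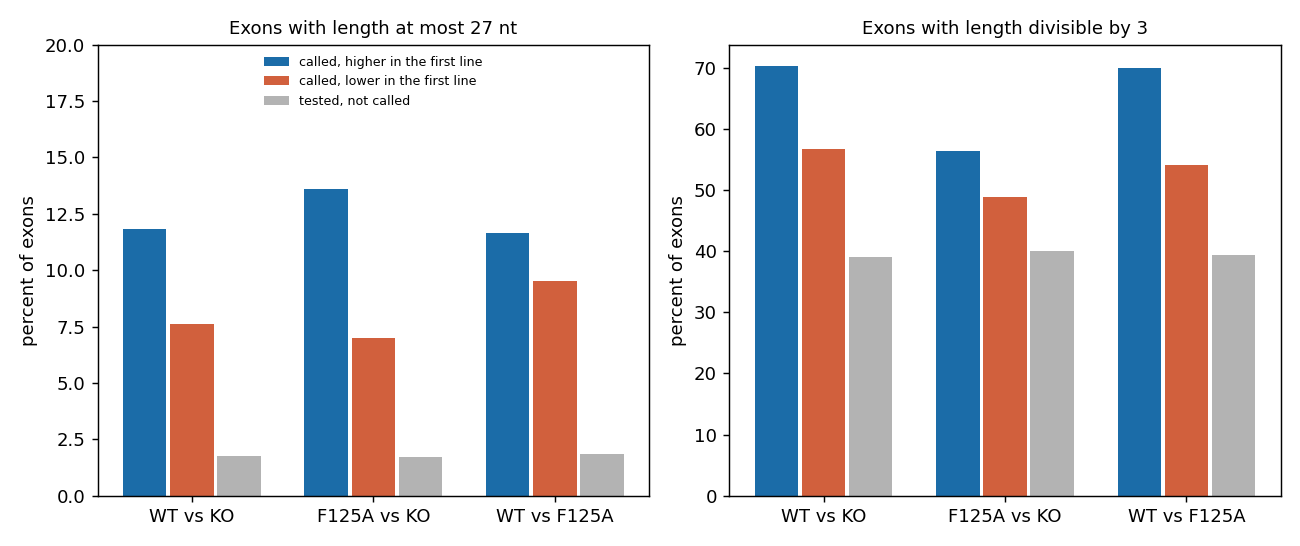
Percent of cassette exons that are at most 27 nt long (left) or have a length divisible by 3 (right), for exons called higher or lower in the first line of each comparison and for tested exons without a call. Short exons make up 11.8% of the exons higher in the WT line and 13.6% of those higher in the F125A line, against 1.76% and 1.71% of the uncalled exons.

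The F125A line was compared with the KO line to find the exons that still differ when the RNA recognition motif is altered. The limit of 1 line per construct applies here too. SPAG9 encodes a scaffold of JNK signalling and kinesin transport, and its 39-nt exon rose from 0.0182 ± 0.0190 in the KO line to 0.80 ± 0.0171 in the F125A line. AFDN encodes an adaptor of cell junctions, and its 21-nt exon rose from 0.205 ± 0.0209 to 0.830 ± 0.0339. A 6-nt exon of NSFL1C, which encodes a cofactor of a membrane-fusion ATPase, rose from 0.0331 ± 0.0151 to 0.681 ± 0.0411. The 48-nt exon of the myosin gene MYO9B rose from 0.132 ± 0.00639 to 0.736 ± 0.0205. The 24-nt exon of SLIT2, which encodes an axon guidance ligand, rose from 0.0440 ± 0.00650 to 0.612 ± 0.0137. MYL6 encodes a myosin light chain, and its 45-nt exon rose from 0.0649 ± 0.00677 to 0.575 ± 0.0191. The 276-nt exon of the kinesin gene KIF1A rose from 0.139 ± 0.0311 to 0.616 ± 0.0510.

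A 365-nt exon of the non-coding RNA HOTAIR, with no matching exon in GENCODE 29, rose from 0.195 ± 0.0563 to 0.893 ± 0.112. TPM1 was among the exons that fell, from 0.965 ± 0.0373 to 0.342 ± 0.0548. A 42-nt exon of WASF3, which encodes a regulator of actin branching, fell from 0.605 ± 0.0297 to 0.142 ± 0.0121. This WASF3 exon also had no matching exon in GENCODE 29. The 183-nt exon of FNBP1, which encodes a membrane-bending protein of endocytosis, fell from 0.596 ± 0.0554 to 0.271 ± 0.0189.

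The exon of SPAG9 (ENSG00000008294.22) spans chromosome 17 from 50975863 to 50975901 on the - strand, and that of AFDN (ENSG00000130396.22) spans chromosome 6 from 167913403 to 167913423 on the + strand. The exon of MYL6 (ENSG00000092841.19) spans chromosome 12 from 56160626 to 56160670 on the + strand. The exon of NSFL1C (ENSG00000088833.18) spans chromosome 20 from 1455714 to 1455719 on the - strand. The exon of SLIT2 (ENSG00000145147.20) spans chromosome 4 from 20525149 to 20525172 on the + strand, and that of KIF1A (ENSG00000130294.18) spans chromosome 2 from 240757319 to 240757594 on the - strand. GENCODE 29 annotates all 6 as coding exons. A library had on average 734 reads for SPAG9, 854 for AFDN, 1632 for MYL6, 437 for NSFL1C, 359 for SLIT2 and 282 for KIF1A. Adjusted p was 9.83e-127 for SPAG9, 3.13e-72 for AFDN, 6.86e-130 for MYL6, 2.86e-46 for NSFL1C, 2.81e-34 for SLIT2 and 6.12e-12 for KIF1A.

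Of 51680 cassette exons tested between the F125A and KO lines, 256 in 160 genes were called. Inclusion was higher in the F125A line for 213 and lower for 43, and the median size of the change was 0.223. The 43 were 25, 24 and 27 without F125A library 1, 2 or 3. The libraries did not overlap in 250 of the called exons, and in 11.3% of all tested exons (chance gives at most 10%). With the deposited FDR 2516 exons were called, 1402 higher and 1114 lower, and with limma on logit PSI 18, of which 18 were higher and 0 lower.

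Cytoskeletal genes held the most called genes here too, with 25 of 81 (22 with a higher and 5 with a lower exon). Among other genes 1.38% had a called exon (Fisher's exact test, adjusted p 6.54e-25). Of 67 signalling genes 13 had a called exon (1.33e-10), among them PLEKHA1, a phosphoinositide-binding adaptor, whose 41-nt exon rose from 0.143 ± 0.0222 to 0.503 ± 0.0440. Of 63 trafficking genes 8 had one (1.84e-05), among them PICALM, a clathrin adaptor gene, whose 24-nt exon rose from 0.0397 ± 0.0195 to 0.332 ± 0.0153. Of 31 neuronal genes 5 had one (0.000256), of 77 chromatin genes 4 (0.0606) and of 64 splicing regulators 2 (0.398). Of 36 known Rbfox targets 12 had one (9.94e-13), among them EPB41, a membrane skeleton gene, whose 63-nt exon rose from 0.0607 ± 0.0120 to 0.383 ± 0.0385. Adjusted over the list alone, the called genes numbered 30 of cytoskeleton, 13 of signalling, 10 of trafficking, 5 neuronal, 5 of chromatin, 4 splicing and 13 of the known targets.

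Of 149 exons in 21 mitochondrial genes 0 were called by the quasi-binomial model and 0 had an unadjusted p below 0.05 with a change of 0.1. The deposited FDR called 3 of them and limma 0. Of 144 exons in the 7 LASR genes 0 were called, 1 had an unadjusted p below 0.05 with a change of 0.1, and the deposited FDR called 2 and limma 0. With 256 of 51680 tested exons called by the quasi-binomial model, its 0 calls among 149 or 144 exons do not show that these genes are spared. Of the exons higher in the F125A line, 29 of 213 (13.6%) were at most 27 nt long, against 1.71% of uncalled exons (odds ratio 9.08, adjusted p 7.02e-17). Their length was divisible by 3 in 56.3%, against 40.1% (adjusted p 2.97e-06). Of the lower exons 3 of 43 (6.98%) were short (adjusted p 0.0396) and 48.8% were divisible by 3 (0.276).

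RBFOX2 itself had 2 called exons in the F125A line. A 74-nt exon on chromosome 22 from 35767368 to 35767441 on the - strand, with no matching exon in GENCODE 29, was listed at a PSI of 0 in the KO libraries and had a PSI of 0.261 ± 0.0494 in the F125A libraries (adjusted p 0.00205, 55.7 reads per library). The 43-nt coding exon from 35752613 to 35752655 rose from 0.0494 ± 0.0737 to 0.562 ± 0.275 (adjusted p 0.00643). Its rise of 0.513 was no longer called without the second F125A library (0.372), the first KO library (0.495) or the third KO library (0.488). In the WT line the PSI of RBFOX2 was 0.0153 ± 0.00580 for the first exon and 0.0745 ± 0.0742 for the second.

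Some exons differed from KO in both lines. Of 42176 exons tested in both tables against KO, 80 were called higher with both and 7 lower with both, together 87, which is 38.7% of the 225 called for F125A and 23.9% of the 364 called for WT. Independent lists of these sizes would share 1.23 higher and 0.0742 lower exons. The exons of SYNE2 (0.407 ± 0.137 in the F125A line), TPM1, SPAG9 (0.350 ± 0.0311 in the WT line), MYO9B (0.485 ± 0.0415 in the WT line), SLIT2 (0.326 ± 0.0302) and NSFL1C (0.469 ± 0.00649) were among the 87. Both comparisons use the same KO libraries, which alone makes differences go together. In 20 simulations of unchanged lines against these KO libraries, on 41189 exons, no exon was called with both in the same direction, against 89 observed there. The simulated lines had no calls for WT and at most 1 for F125A, against 362 and 220 observed. Their overlap was therefore bound to be 0 and does not show how many shared calls the common KO libraries produce. The covariance of the differences was 0.00257, against 0.00184 simulated (highest 0.00196). The simulated covariance includes the shared controls at the fitted dispersions, and the observed one lies above it. A fitted dispersion is common to both lines of a comparison. In the tables against KO, PSI correlated at r of at most 0.9576 between KO libraries. Within the other lines r was at least 0.9612. The simulation may therefore understate the spread of the KO libraries, so the covariance does not show an excess over the shared controls. For the number of shared exons, the 3 KO libraries cannot be split into separate controls for each line. Part of its excess over independent lists may therefore come from the shared controls.

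**Figure D2:**
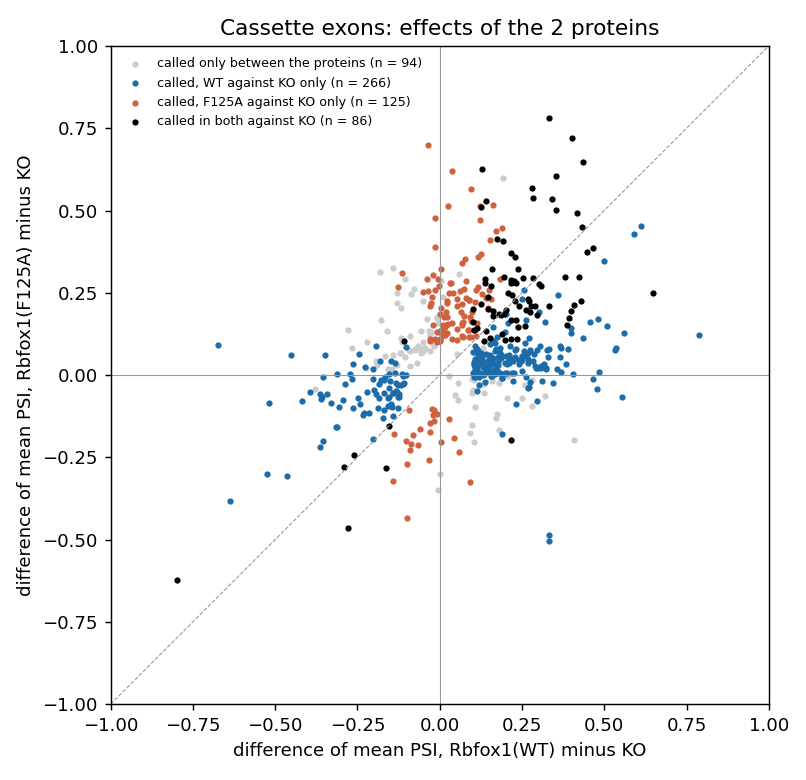
Difference of mean PSI from the KO line for the WT line (horizontal) and the F125A line (vertical), for 571 cassette exons tested in all 3 tables and called in at least 1. Each point is an exon, and the dashed line marks equal effects. Of these, 266 were called against KO for WT and not for F125A, 86 for both, and 94 only between the proteins.

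The WT and F125A lines were compared directly, since a call against KO for only 1 protein does not show that the proteins differ. The exon of ACTN2 reached 0.814 ± 0.0585 with WT and 0.147 ± 0.134 with F125A (adjusted p 1.22e-09). PTBP2 reached 0.672 ± 0.181 and 0.196 ± 0.0921 (6.72e-07). The 37-nt exon of ATP5F1C was at 0.682 ± 0.0263 with WT and 0.998 ± 0.00265 with F125A (1.31e-82), the latter beside 0.995 ± 0.00213 in the KO line. The 93-nt exon of ANK2, which encodes an ankyrin, was at 0.420 ± 0.0481 and 0.00202 ± 0.00349 (4.76e-33). The 60-nt exon of MFF was at 0.458 ± 0.00902 and 0.244 ± 0.0262 (2.35e-07).

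Other exons were included more with F125A than with WT. AFDN was at 0.332 ± 0.0288 with WT and 0.830 ± 0.0339 with F125A (adjusted p 4.62e-52). MYL6 was at 0.190 ± 0.0157 and 0.575 ± 0.0191 (1.10e-69), and the 276-nt exon of KIF1A at 0.124 ± 0.0320 and 0.616 ± 0.0510 (3.68e-19). HOTAIR was at 0.159 ± 0.0370 and 0.893 ± 0.112 (3.11e-20). The 59-nt exon of CAMK2G, which encodes a calcium-dependent kinase, was at 0.0458 ± 0.0379 and 0.425 ± 0.0442 (2.46e-14). The 57-nt exon of INF2 was at 0.338 ± 0.0699 and 0.852 ± 0.0587 (1.72e-07).

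**Figure D3:**
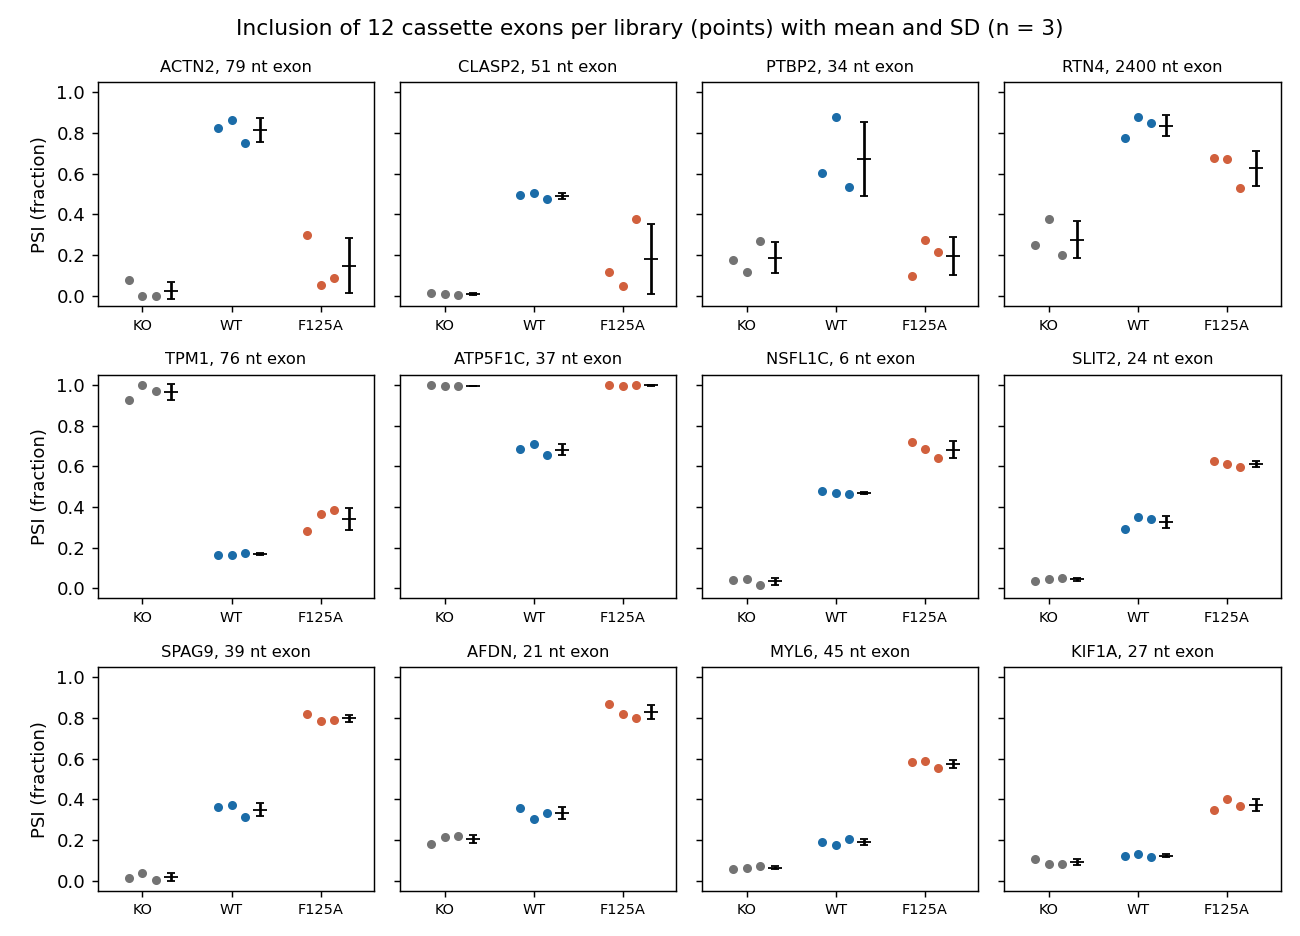
PSI per library of 12 cassette exons in the KO, WT and F125A lines. Points are libraries, and the marks beside them give the mean and SD (n = 3). ACTN2, CLASP2, PTBP2, RTN4, TPM1 and ATP5F1C had the larger mean change from KO with WT, and NSFL1C, SLIT2, SPAG9, AFDN, MYL6 and KIF1A (27-nt exon, chosen after its values were seen) with F125A.

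Of 56236 exons tested between the WT and F125A lines, 465 in 335 genes were called, 223 higher with WT and 242 higher with F125A. The median size of the change was 0.202. The libraries did not overlap in 448 of them, and in 13.0% of all tested exons (chance gives at most 10%). With the deposited FDR 2832 were called, and with limma on logit PSI 46. Of the 448 exons called for WT against KO, 435 were tested here and 214 (49.2%) were called in the direction of their change with WT, while 17 were called in the opposite direction. Of the 256 exons called for F125A against KO, 241 were tested here and 113 (46.9%) were called in the direction of their change with F125A, while 7 were called in the opposite direction. These exons were chosen in comparisons that use the same WT or F125A libraries, which raises both shares.

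Genes of cytoskeleton and adhesion had a called exon between the proteins in 33 of 82 cases (19 with an exon higher with WT and 16 with one higher with F125A, adjusted p 6.12e-27). Called genes numbered 19 of 67 in signalling (6.39e-13), 19 of 64 in trafficking (3.37e-13), 9 of 76 in chromatin (0.00144), 6 of 32 neuronal (0.00110), 4 of 22 mitochondrial (0.00767), 4 of 64 splicing (0.201) and 16 of 36 known Rbfox targets (2.89e-14). Adjusted over the list alone, they numbered 39 of cytoskeleton, 25 of signalling, 19 of trafficking, 11 of chromatin, 10 neuronal, 4 mitochondrial, 4 splicing and 20 of the known targets. Of 159 exons in the 7 LASR genes 0 were called, 0 had an unadjusted p below 0.05 with a change of 0.1, and the deposited FDR called 1 and limma 0. With 465 of 56236 tested exons called, 0 among 159 does not show that LASR genes are spared. Exons of at most 27 nt made up 11.7% of those higher with WT and 9.50% of those higher with F125A, against 1.83% of uncalled exons (adjusted p 4.47e-13 and 5.47e-10). Length was divisible by 3 in 70.0% and 54.1%, against 39.4% (1.61e-19 and 5.79e-06).

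Events of other types were called too. A read can count in several events, so some of them may repeat a change of a cassette exon, which was not counted. ACTN2 and WASF3, named here, also had a called cassette exon. In the WT line an alternative 3′ splice site of CACNA2D1, which encodes a calcium channel subunit, rose from 0.0196 ± 0.0179 to 0.396 ± 0.0335 (adjusted p 2.00e-21). An alternative 3′ splice site of the membrane skeleton gene EPB41L3 fell from 0.956 ± 0.0761 to 0.234 ± 0.0551 (1.04e-04). A retained intron of ACTN2 fell from 1 in all KO libraries to 0.208 ± 0.0193 (2.20e-05). In the F125A line a mutually exclusive exon of WASF3 fell from 0.737 ± 0.0214 to 0.204 ± 0.0239 (4.68e-23). An alternative 3′ splice site of LAS1L, a ribosome assembly gene, rose from 0.285 ± 0.0648 to 0.635 ± 0.0769 (9.13e-12), and a retained intron of the kinase gene TAOK2 fell from 0.941 ± 0.00347 to 0.571 ± 0.0158 (1.15e-06). Between the proteins, EPB41L3 was at 0.234 ± 0.0551 with WT and 0.959 ± 0.0704 with F125A (1.32e-08).

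Of 69953 such events tested for WT against KO, 225 were called (81 higher and 144 lower), namely 63 alternative 3′ splice sites, 28 alternative 5′ splice sites, 112 mutually exclusive exons and 22 retained introns (34 without the first WT library). The libraries did not overlap in 36, 18, 107 and 20 of them, and in 9.96%, 11.2%, 12.5% and 12.6% of all tested events of these types (chance gives at most 10%). For F125A against KO, 154 of 65222 were called (76 higher and 78 lower), namely 40, 16, 78 and 20 of these types (32 retained introns without the first KO library). The libraries did not overlap in 22, 13, 74 and 15 of them, and in 9.50%, 9.66%, 11% and 11.2% of all tested. Between WT and F125A, 223 of 71426 were called (86 higher with WT and 137 lower), namely 36, 44, 120 and 23 (25 alternative 5′ splice sites without the first F125A library). The libraries did not overlap in 25, 36, 114 and 22 of them, and in 9.46%, 10.4%, 12.5% and 11% of all tested. With no coverage minimum the retained introns were 42, 39 and 43 in the 3 comparisons.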

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

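The search for exons that the proteins move in opposite directions, and the tests of KO libraries that stand apart, of a weaker effect on all exons and of a difference between lines, were chosen only after the results were seen. The comparison between the proteins was planned.

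FNBP1 and DEPDC1 each had an exon called in opposite directions with the 2 proteins. The 153-nt coding exon of FNBP1 on chromosome 9 from 129923844 to 129923996 had a PSI of 0.617 ± 0.0912 in the WT line, 0.401 ± 0.0271 in the KO line and 0.203 ± 0.0187 in the F125A line. It drew attention because it was called higher than KO with WT and lower with F125A. WT minus F125A was 0.413 (adjusted p 1.99e-29 from the quasi-binomial model). It shares an end with the 183-nt exon of FNBP1. The 852-nt coding exon of DEPDC1, a gene of dividing cells, on chromosome 1 from 68482046 to 68482897, was at 0.176 ± 0.0131, 0.285 ± 0.0164 and 0.388 ± 0.00689 in the same order. WT minus F125A was -0.212 (adjusted p 1.27e-57). In both exons WT minus F125A follows from the differences the exons were selected for and is no separate evidence. The call of DEPDC1 against KO in the F125A line was lost without the third F125A library (a rise of 0.0992) or the second KO library (0.0951), since the change then fell below 0.1.

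Exons of ACTN2, PTBP2 and ATP5F1C changed more with wild-type Rbfox1, and exons of AFDN, MYL6 and KIF1A changed more with F125A. By the direct test between the lines, 214 exons called for WT against KO differed in the direction of their change with WT, and 113 exons called for F125A against KO differed in the direction of their change with F125A. If KO libraries that stand apart from both other lines made the F125A calls, few of these exons would differ between WT and F125A, where KO is not used. Of those tested there, 46.9% did, in the matching direction. The choice of exons used the same F125A libraries, which raises this share by an amount not measured here. It speaks only for the exons that differed. Another 61 exons were called against KO in both lines and not between the proteins, so KO libraries that stand apart stay open for them. A mutant protein with a smaller effect on all exons would leave few of the 113. How many the choice of exons alone would leave was not simulated. Also open is a difference between separately grown lines that does not come from the protein. With 1 line per construct it cannot be told apart from an effect of the substitution. Against KO it cannot be told apart from an effect of either protein. An effect of the substitution on which exons Rbfox1 changes stays open too, as untested.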

How the results depend on the processing

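The events with read lists intact or split in 1 way only, the depth trend and the left-out libraries for the overlap and for exons that also differ between the proteins were chosen as alternatives after seeing the data. Values are given in the order WT against KO, F125A against KO, WT against F125A. With a PSI threshold of 0.2 the cassette exons called were 232, 151 and 235, the other events 134, 98 and 116, the exons shared by both proteins 42, and the WT exons that also differ between the proteins 100. A higher threshold keeps fewer events by construction. With the deposited rMATS FDR the cassette exons were 3363, 2516 and 2832 and those that also differ between the proteins 1020. The other events were 3474 (other event types called, Rbfox1_WT against KO), 2926 (other event types called, Rbfox1_F125A against KO) and 3029 (other event types called, Rbfox1_WT against Rbfox1_F125A), and the overlap of Rbfox1_WT and Rbfox1_F125A effects held 826 exons. The share with higher inclusion moved as well: in place of 330 of 448 and 213 of 256 against KO, it was 1657 of 3363 and 1402 of 2516. With limma on logit PSI the cassette exons were 124, 18 and 46 and the other events 33, 43 and 26. In 1 fit over all 3 lines the other events were 131, 100 and 122, while cassette exons stayed within 1.5 times. The 1 fit holds only events listed in all 3 comparisons, so fewer were tested. For WT against KO, mutually exclusive exons fell from 20440 to 8814 tested and from 112 to 53 called. Beyond this, the causes were not tested for the deposited FDR, limma and the 1 fit. All 176 named events called in the 3 comparisons stayed called with the deposited FDR, and 138 of them were not called by limma, with no direction reversed. The totals over cassette exons and over other event types stayed within 1.5 times with a PSI threshold of 0.05, coverage minimums of 10, 50 or none, every event, no dispersion floor, no depth trend, and events with lists intact or split in 1 way. Smaller counts moved more. With no coverage minimum retained introns were 42, 39 and 43 in place of 22, 20 and 23. With a PSI threshold of 0.05 alternative 5′ splice sites for F125A against KO were 27 in place of 16, and other events higher than KO were 123 in place of 81 (WT) and 117 in place of 76 (F125A).

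With 1 library left out, cassette exons called ranged from 354 to 393, from 186 to 223 and from 346 to 406, and other events from 202 to 223, from 128 to 181 and from 191 to 219. The shared exons ranged from 67 to 78, and those that also differ between the proteins from 167 to 195. The largest change of these totals was 1.38 times. Smaller counts moved by over 1.5 times. Cassette exons lower in the F125A line than in KO were 25, 24 and 27 without F125A library 1, 2 or 3, in place of 43. Alternative 5′ splice sites for WT against F125A were 25 without the first F125A library, in place of 44. Retained introns were 34 without the first WT library, in place of 22 (WT against KO), and 32 without the first KO library, in place of 20 (F125A against KO). Of the 176 named events 61 lost their call in at least 1 of these fits, and none changed direction. In simulated tables a PSI change of 0.2 was called in 26% to 40% of cassette exons.

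No paired analysis was possible because the read lists do not name the replicate of each value, so a replicate block could not be fitted. edgeR, DESeq2 and the motif tests were not run.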

Other observations

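The counts over other splits of the libraries, the tests of lists split with a tie, of calls outside the real split, of PTBP2 reads, and the grouping of short exons by protein were chosen only after the results were seen. The matched draws and the share of short exons among calls of other splits were planned before their results were seen.

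Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05. For cassette exons the real split called 448 (WT against KO), 256 (F125A against KO) and 465 (WT against F125A) exons, and the highest of the other splits 24, 23 and 28. For the other event types it called 225, 154 and 223 events, and the highest other split 37, 35 and 20. Only 1 split, the real one, reached its own count in each case.

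Short exons such as the 21-nt exon of AFDN were frequent among the calls. Exons of at most 27 nt were 48 of 448 called for WT against KO (10.7%) and 32 of 256 for F125A against KO (12.5%). In 1000 draws of uncalled exons matched on reads and mean PSI they were 1.99% on average (highest 4.46%) and 1.90% (highest 5.47%), which argues against read depth and starting inclusion as the cause. Among calls of the other 9 splits they were 4.94% (8 of 162) and 22.2% (34 of 153). By the criterion written before, the first value speaks against noise of short exons in the test and the second for it, but that criterion was wrong for both: the other splits still part the lines 2 libraries to 1, and all 8 and all 34 of these short calls are also calls of the real split. Among the calls the real split does not make, short exons were 0 of 30 and 0 of 27, with upper 95% limits (exact Clopper-Pearson) of 11.6% and 12.8%, too wide to decide, so noise of short exons cannot be told apart from a real excess by these splits.

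The WT and F125A lines differed in which short exons were called. Of exons tested in all 3 tables, 23 short ones were called against KO for WT only, 16 for F125A only and 14 for both. Of the 16, 13 were called between the proteins, 12 of them with higher inclusion in the F125A line. Among them, chosen after their values were seen, the 18-nt exon of DST, which encodes a cytoskeletal linker, was at 0.626 ± 0.0313 (KO), 0.631 ± 0.0238 (WT) and 0.95 ± 0.0170 (F125A). The 27-nt exon of the myosin gene MYO6 was at 0.134 ± 0.0141, 0.0835 ± 0.0300 and 0.386 ± 0.0570, and the 15-nt exon of the spectrin gene SPTAN1 at 0.159 ± 0.00698, 0.124 ± 0.00821 and 0.415 ± 0.0704. Of the 23, 15 were called between the proteins, 14 of them with higher inclusion in the WT line. Both directions follow in part from the choice of exons, which used the same libraries. Also chosen after their values were seen, the 21-nt exon of the dynactin gene DCTN1 was at 0.0283 ± 0.0109, 0.280 ± 0.0306 and 0.0397 ± 0.0342, and the 9-nt exon of PSAP, a lysosomal protein gene, at 0.0677 ± 0.0151, 0.309 ± 0.0104 and 0.115 ± 0.0289.

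Read lists that had to be split with a tie do not account for the total numbers of calls. Without such events the number called changed by at most 1.04 times for cassette exons and 1.2 times for other event types together. Single types moved more. Retained introns for F125A against KO were 14 in place of 20, and alternative 3′ splice sites for WT against KO 46 in place of 63. Retained introns for WT against KO stayed at 22. Ties were rarer among called than tested cassette exons (8.26% against 17.2% for WT against KO) and more frequent among the other called events (17.8% against 10.3%). For F125A against KO, the share with a tie among called events differed by type. It was 0% for alternative 5′ splice sites (12.3% of tested) and 30% for retained introns (3.9% of tested).

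PTBP2, whose 34-nt exon was included more in the WT line, also had more reads there. Reads of the deepest cassette event of this gene (chromosome 1 from 96804800 to 96806452) in ppm of the reads over 74669 events were 17.6 ± 1.93 in the WT line, 13.1 ± 0.890 in the KO line and 11.7 ± 1.90 in the F125A line. The exact permutation p was 0.1 for WT against KO and for WT against F125A, the smallest that 3 against 3 libraries allow, and 0.3 for F125A against KO (two-sided). The ratio of WT to KO was 1.34. Deeper WT libraries are not the cause, since the deepest WT library had 1.04 times the event reads of the shallowest KO library, while PTBP2 reads before scaling were at least 1.10 times higher in each WT library than in each KO library. The event ends where the 34-nt exon ends, so its reads may rise with inclusion of that exon at an unchanged amount of transcript. The reads therefore do not measure the expression of PTBP2.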
